A study of Mus musculus with 2 samples.

How the data were processed

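H3K9ac was measured by chromatin immunoprecipitation and sequencing in whole hearts of mouse embryos at day 15.5, in 2 biological replicates, each a pool of embryos (78 and 62), with fragments of 300 to 500 bp per the labels. The processed data were 4 peak lists in narrowPeak format on the mm10 build. Per the labels and the deposited descriptions, peaks were called against a control alignment on replicate 1, on replicate 2 and on both together, and the replicated list was derived from the pooled and the per-replicate lists. The caller, its version, the aligner and the rule for the replicated list are not given in the sources used here. Each peak's signal value is the authors' own deposited value for its enrichment, whose exact definition is not given in the sources used here, and it was used only to describe and rank peaks within one list. The deposited −log10 p and −log10 q values are the peak caller's. The lists hold no read totals, so the depth is unknown and no value carries a depth-based error. Every list reached down to a −log10 p of about 2, so a gene without a peak is one where none was called, not one shown to lack the mark.

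All 32185 replicated peaks were found in the pooled list under the same position. All 27442 pooled peaks with an overlap of at least 50% of either peak in both replicates were in the replicated list, and 4743 replicated peaks (14.7%) had no such overlap in both. For 4611 of these, at least 1 replicate had no overlapping peak at all. The replicated list was used for the main results, and the same value was taken from the lists of replicates 1 and 2 to show their spread. These lists are longer than the replicated list, so their spread is not the error of its value.

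Peaks were compared with GENCODE vM21 genes on the GRCm38 (mm10) genome, whose chromosome lengths no peak exceeded. Of 21938 protein-coding genes, 21911 with a symbol of their own were used, keeping the longest for each symbol. A gene was marked when a peak overlapped the 1 kb on either side of any annotated transcript start. Domains were replicated peaks joined over gaps of up to 1 kb, and a gene's width was that of the widest domain at its starts. Distal peaks lay more than 2.5 kb from every protein-coding start and were counted within 50 kb of a gene's starts. Replicate overlap (at least 1 bp) and the share at starts were set against 100 circular shifts within chromosomes. CpG observed over expected was taken from the 1 kb on either side of a gene's 5′ end. Shares carry 95% Wilson intervals, which cover counting error over peaks or genes only.

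The 24 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Each list's marked members were compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists, at an adjusted threshold of 0.05, and the direction had to hold in both replicates' lists. Widths and distal counts were set against 10000 random lists of the same size and called apart above the percentile 97.5 or under 2.5, with no p-value. Genes are not replicates, so these tests describe these lists. Log2 odds ratios had 0.5 added to each count. By the rule for named genes, the text names up to 4 marked members with the widest domains in each list higher than the background, up to 6 unmarked members of such heart lists, up to 3 marked members of the other lists, the 10 genes with the widest domains, the 5 distal peaks of highest signal and the 5 widest domains at no protein-coding start. Other genes were named after their values were seen.

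The steps were tested on simulated data with 21911 genes. Of 10 lists of 20 genes simulated as nearly all marked, the list test called 9 higher; of 10 seldom marked, it called 10 lower; and of 20 unchanged lists, it left 20 uncalled. The width step called all 10 lists simulated as wide and left 19 of 20 unchanged lists uncalled, and the distal step did the same. Simulated marks lay at gene 5′ ends, which alone were searched for marks and widths, and no gaps were joined. Joining over 1 kb and the choice among several starts were therefore not tested. For independent simulated peaks, the overlap was 93.7% of that of shifted peaks. Repeated sequence around gene starts was counted as the share of 32 bp words within 1 kb of a 5′ end that occur elsewhere in the 66 sequences of the primary assembly. The 173 patch and alternate-locus sequences of the reference repeat primary sequence. A first count had included them, and they were then taken out and counted separately. On simulated sequence this count gave 49.2% for 50 windows made with 49.2% repeated words, and 0% for 100 windows made without. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

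Alternatives changed 1 choice at a time: replicate overlap of at least 50% of both peaks, lists of equal length, start windows of 0.5 and 2.5 kb, gene 5′ ends only, joined gaps of 0 and 3 kb, distances of 25 and 100 kb, peaks with a −log10 q of at least 5, the pooled list, each replicate's own list in place of the replicated list, and random lists matched on −log10 p or gene density, CpG content within 0.5 kb, and the X comparison without olfactory receptors. The background without olfactory receptors and the list of replicated peaks with an overlap of at least 50% in both replicates were added after the data were seen.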

Results

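Acetylation of lysine 9 of histone H3 (H3K9ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in the mouse heart at embryonic day 15.5. The series held 1 group of 2 biological replicates from C57BL/6 embryos of both sexes. Replicate 1 was a pool of 78 embryos and replicate 2 a pool of 62 embryos. Peaks had been called on each replicate (52082 and 55008 peaks), on both together (63830 peaks), and a replicated list of 32185 peaks had been drawn from the pooled list. The lists give no read totals, so the depth behind each peak was unknown. With 1 group, the only comparison between samples was that of the replicates, and all other comparisons were made within the peak lists, where genes are not replicates. A gene was called marked when a peak reached within 1 kb of one of its annotated transcript starts.

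The strongest acetylated sites were shared by both replicates, and the weakest mostly were not. Of the replicate 1 peaks, 61.0% overlapped a replicate 2 peak (95% Wilson interval 60.6 to 61.5%), against 2.40% ± 0.147 (SD of 100 circular shifts). In the other direction 57.9% overlapped (57.5 to 58.3%), against 2.30% ± 0.152 for shifted peaks. In the strongest decile of each list by −log10 p, 100% of peaks overlapped, and in the weakest decile 25.7% of replicate 1 and 21.5% of replicate 2 peaks did. Peaks without a partner were narrow, with a median of 223 bp in replicate 1 and 217 bp in replicate 2, and 16.3% and 17.5% of them lay at a protein-coding start. Of the peaks with a partner, 64.8% did in each list. Across 28546 matched peaks, which are not independent replicates, Spearman's rho was 0.86 for the signal value and 0.84 for peak width. At the level of genes the replicates differed less: 13745 protein-coding genes were marked in both, 387 in replicate 1 alone and 485 in replicate 2 alone. Requiring each peak of a pair to be covered by at least 50% lowered the overlap to 43.7% and 41.4%, and keeping only peaks with a −log10 q of at least 5 raised it to 86.1% and 86.4%.

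**Figure D1:**
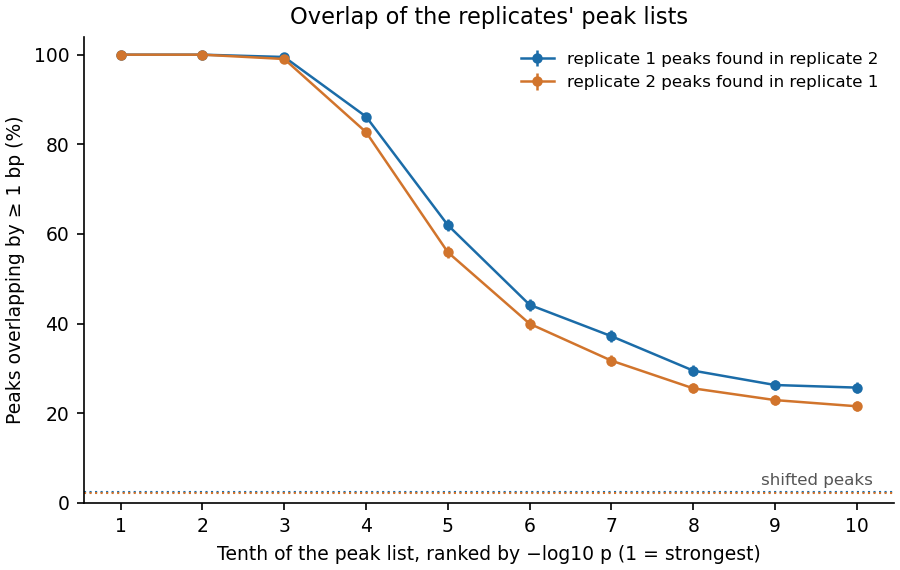
Share of each replicate's peaks (%, vertical axis) that overlap a peak of the other replicate, by decile of its list ranked by −log10 p (horizontal axis, 1 is the strongest decile). Bars are 95% Wilson intervals, mostly smaller than the points, and dotted lines are the means of shifted peaks (2.40% and 2.30%); the overlap is 100% in the strongest decile and 25.7% and 21.5% in the weakest.

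H3K9ac peaks were concentrated at the starts of genes. Of the 32185 replicated peaks, 19281 (59.9%) overlapped the 1 kb around a protein-coding start, 10.5 times the 5.71% ± 0.298 of shifted peaks (SD of 100 shifts). The share was 45.9% in the list of replicate 1 and 44.9% in that of replicate 2 (45.4% ± 0.735, SD, n = 2), and 38.7% in the pooled list. By peak summit, 57.7% lay at a protein-coding start, 4.22% at the start of another gene, 4.32% in an exon, 22.1% in an intron and 11.7% between genes. Shifted summits lay in introns in 40.3% and between genes in 49.9% of cases. Peaks at starts had a median width of 1063 bp, and the 10437 peaks more than 2.5 kb from every protein-coding start had one of 480 bp. In all, 13903 of 21911 protein-coding genes (63.5%) were marked, with 64.5% and 64.9% in the lists of replicates 1 and 2 (64.7% ± 0.316, SD, n = 2).

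Genes of the heart muscle cell were nearly all marked. All 26 cardiac transcription factors carried a peak, as did 25 of 26 sarcomere genes, 18 of 20 genes of ion handling and peptide hormones, 12 of 12 ventricular genes and 23 of 24 genes of fatty acid and oxidative metabolism, against 63.4% of all other genes for each of these lists. The adjusted p of Fisher's exact test (two-sided, Benjamini-Hochberg over 24 lists) was 4.22e-05 for the transcription factors, 0.000394 for the sarcomere, 0.0221 for ion handling, 0.0088 for the ventricular list and 0.000895 for metabolism. Each direction held in both replicates' own lists. The 30 cardiac signalling genes, among them Igf2, Bmp7 and Vegfa, were all marked (adjusted exact p = 6.53e-06). The unmarked members were Myom2 of the sarcomere list, Nppa and Sln of the ion handling list, and Ckmt2, a mitochondrial creatine kinase of muscle. Myom2 was marked in the pooled list, and the nearest replicated peak to a Ckmt2 start lay 2.18 kb away, so that 24 of 24 metabolic genes were marked within 2.5 kb. Nppa, which encodes atrial natriuretic peptide, had no peak at its start in any of the 4 lists, and the nearest replicated peak lay 12.6 kb away. Sln, which encodes the calcium pump regulator sarcolipin, was marked in the list of replicate 1 and in the pooled list. The atrial list, which also holds Nppa and Sln, had 10 of 12 members marked and did not pass (adjusted exact p = 0.252), with Tbx5, Nr2f2 and Pitx2 having its widest domains (12.7, 7.46 and 2.65 kb, with 4.62 kb at Pitx2 in replicate 1).

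Among the other cell types of the heart, endothelial and endocardial genes were marked in 18 of 20 cases (adjusted exact p = 0.0221), with wide domains at Notch1, Egfl7, Fli1 and Nfatc1, and no replicated peak at Tie1 and Vwf. Tie1 was marked in the list of replicate 1 and Vwf in that of replicate 2. Both were marked in the pooled list, where 20 of 20 members were. All 14 smooth muscle and pericyte genes were marked (adjusted exact p = 0.00579), with the widest domains at Cspg4, Smtn, Synpo2 and Abcc9. The smooth muscle call was lost in the list of replicate 1, with strict peaks (−log10 q of at least 5) and with replicated peaks that overlap both replicates by at least 50%, with 12 of 14 marked in each (adjusted exact p = 0.182, 0.11 and 0.116). The endothelial call was lost with gene 5′ ends only, with 15 of 20 marked (adjusted exact p = 0.289), and with the peaks that overlap both replicates, with 16 of 20 marked (0.187 by the same exact test). Epicardial genes were marked in 10 of 15 cases, among them Wt1, Tbx18 and Sema3d (adjusted exact p = 1). Fibroblast and valve genes were marked in 11 of 16 cases, among them Col1a1, Sox9 and Pdgfra (adjusted exact p = 0.833), with 10 in replicate 1 and 14 in replicate 2, and in the pooled list 15 were marked and the list passed (adjusted exact p = 0.0235). Of 18 erythroid genes 7 were marked, among them Ank1, Tal1 and Sptb (adjusted exact p = 0.0535); in the lists of replicates 1 and 2, each with 7 marked, the adjusted exact p was 0.037 and 0.0346.

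Genes of other tissues were seldom marked, and so were those of macrophages and lymphocytes, cells that a dissected heart could hold. These shares were set against all other genes, not against genes of like CpG content at the 5′ end. Of the hepatocyte, macrophage and lymphocyte, skeletal muscle, and lung and gut lists, 14, 13, 8 and 6 genes lay in the lowest CpG tercile. There 15.3% of all genes were marked, and none of these lists passed as lower than the tercile's other genes. Whether CpG content or tissue lies behind their low shares was therefore not settled. None of 17 macrophage and lymphocyte genes had a replicated peak (adjusted exact p = 2.93e-07), 1 of 20 hepatocyte genes did (Trf, which encodes transferrin; 3.83e-07 by the same exact test) and 3 of 20 skeletal muscle genes did (Mylpf, Tnni2 and Actn3; 4.22e-05 by the same exact test). In the lists of replicates 1 and 2 and the pooled list, 1, 3 and 4 of the macrophage and lymphocyte genes and 6, 5 and 8 of the skeletal muscle genes were marked, still lower than the background in each. The pluripotency and germ line list had 3 of 15 marked, Esrrb, Dazl and Sox2 (adjusted exact p = 0.00139), and 1 of 1134 olfactory receptor genes was marked, Olfr94 (log2 odds ratio -10.58). Lower shares were also found for neuronal genes (7 of 20, among them Camk2a, Elavl4 and Map2; adjusted exact p = 0.0157), lung and gut epithelium (5 of 16, among them Epcam, Cdh1 and Foxa1; 0.0221 by the same exact test) and the Hox clusters (18 of 39, among them Hoxb2, Hoxb4 and Hoxa2; 0.036 by the same exact test). Each of these 3 calls was lost in the pooled list (adjusted exact p = 0.663, 0.468 and 0.142) and in the list of 1 replicate. In replicate 1, 12 of 20 neuronal genes were marked (adjusted exact p = 0.707), and in replicate 2, 8 of 16 lung and gut genes (0.32 by the same exact test) and 21 of 39 Hox genes (0.204 by the same exact test) were. The Hox call was also lost with starts within 2.5 kb, with 19 of 39 marked (adjusted exact p = 0.051). All 20 cell cycle genes (among them Ccnd2, Ccnd1, Tk1 and Pcna), all 17 housekeeping genes (among them Actb, Gapdh, Ubc and Polr2a), all 22 enzymes and readers of histone acetylation (among them Hdac5, Kat2b, Hdac7 and Kat6b) and 80 of 83 ribosomal protein genes (among them Rpl13a, Rps11, Rpl18 and Rps2) were marked, all past the test with adjusted exact p = 0.000485, 0.00117, 0.000188 and 1.19e-11. The histone acetylation call was lost with gene 5′ ends only, with 18 marked (adjusted exact p = 0.0605).

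**Figure D2:**
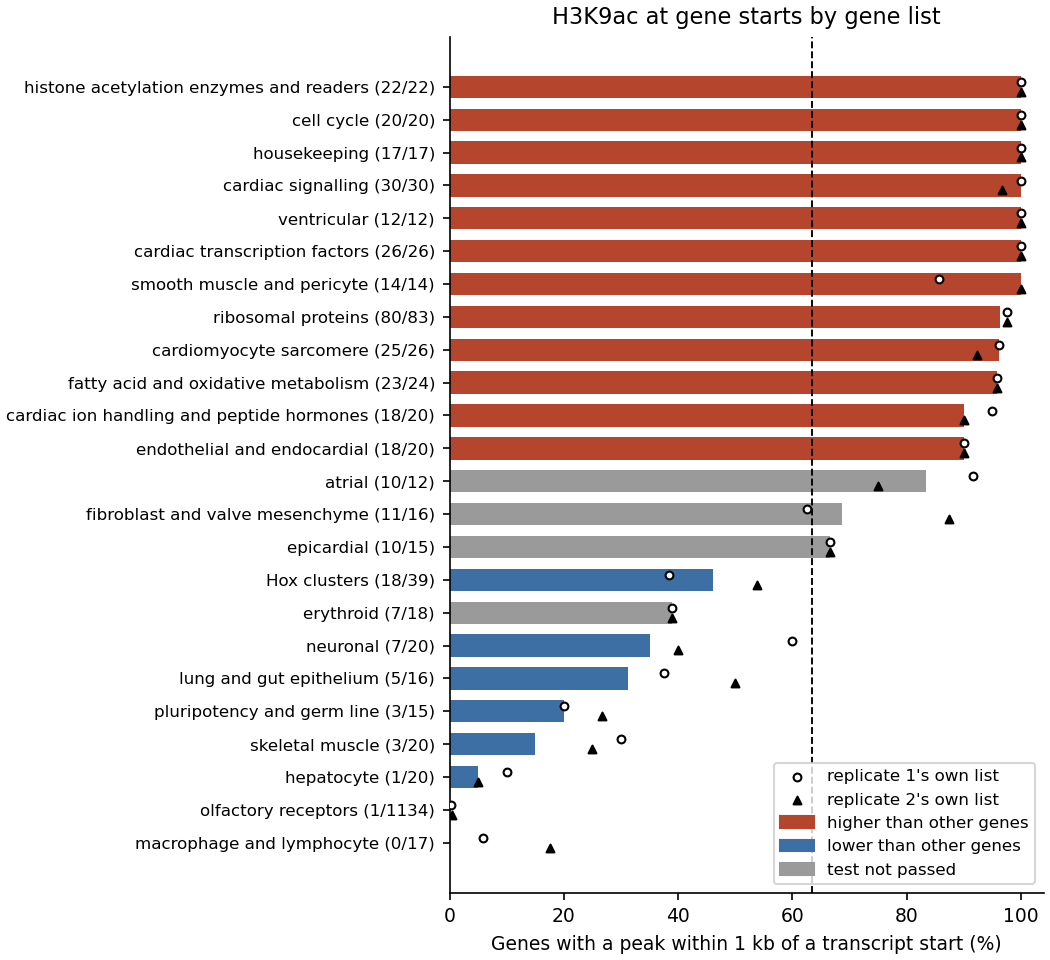
Share of each gene list's members with a replicated peak within 1 kb of a transcript start (%, bars, with marked and total members beside each name). Open circles and triangles give the same share in the lists of replicates 1 and 2. The dashed line is the 63.5% of all protein-coding genes. The lists of heart muscle cells lie above this line, and those of other tissues and of macrophages and lymphocytes below it.

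Cardiac genes carried the widest acetylated domains. Joining replicated peaks over gaps of up to 1 kb, the domain at a marked gene had a median width of 1.80 kb. The widest of all lay at Gata4, a cardiac transcription factor, and covered 22.0 kb (mm10, chromosome 14, 63234884 to 63256897). It was followed by 20.7 kb at Myh7 (chromosome 14, 54977762 to 54998431), the beta heavy chain of cardiac myosin, a domain that also reached within 1 kb of the start of the gene Gm17428, then by 17.8 kb at Hand2 (chromosome 8, 57311957 to 57329755) and 17.7 kb at Nkx2-5 (chromosome 17, 26835979 to 26853648). Irf2bp2 (15.8 kb), Nfib (15.5 kb), Bahcc1 (15.3 kb), Mef2d (15.2 kb) and Gata6 (14.7 kb) completed the 10 widest. Domains called from one replicate differed at some of them, with 10.7 and 10.9 kb at Nkx2-5, 13.0 and 8.07 kb at Bahcc1 and 25.6 and 17.2 kb at Gata4, while Myh7 had 21.2 and 21.6 kb. The median width was 6.84 kb for the 25 marked sarcomere genes, 6.48 kb for the 26 transcription factors and 6.43 kb for the 12 ventricular genes, each at the percentile 100 of 10000 random lists of marked genes of its size. In the lists of replicates 1 and 2 these medians were 6.81 and 6.53 kb, 5.54 and 6.15 kb, and 5.63 and 5.92 kb. Tnni3 (12.2 kb), Myh6 (11.8 kb) and Tnnt2 (11.6 kb) followed Myh7 in the sarcomere list, and Tnni3 had 13.9 and 6.86 kb in the lists of replicates 1 and 2. In the ventricular list, which shares Myh7 with the sarcomere list, Irx5 (8.45 kb), Hey2 (7.32 kb) and Myl2 (7.11 kb) had wide domains.

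Other lists stood apart by less. The median was 3.69 kb for cardiac signalling, 3.43 kb for ion handling (among them Jph2, Atp2a2, Slc8a1 and Ryr2, 8.85 to 6.46 kb, with 3.23 kb at Ryr2 in replicate 1), 3.28 kb for housekeeping, 3.26 kb for fibroblast and valve, 3.11 kb for endothelial, 2.68 kb for fatty acid metabolism (among them Ppargc1a, Slc25a4, Fabp3 and Esrra), 2.66 kb for histone acetylation, 2.65 kb for cell cycle and 2.44 kb for ribosomal protein genes, all above the central 95% of random lists. In the list of replicate 2 alone, the fibroblast and endothelial lists fell within the random range, at the percentiles 83.5 and 95.2. Without joining peaks across gaps, the housekeeping, cell cycle, histone and fibroblast lists did too, at the percentiles 81.6, 88.5, 86.6 and 85.7. Against random lists matched on −log10 p, so did the histone (96.3) and ribosomal (86.2) lists. The atrial (2.63 kb), smooth muscle (1.79 kb), erythroid (1.78 kb) and epicardial (1.28 kb) lists lay within the random range. The atrial list lay above it in the lists of replicates 1 and 2, at the percentiles 98.3 and 99.5, and the epicardial list below it in that of replicate 2, at 1.90. Against random lists matched on −log10 p, the atrial and smooth muscle lists lay above the range, at the percentiles 99.3 and 99.1. Marked genes of the neuronal (0.784 kb), lung and gut (0.692 kb) and Hox (0.652 kb) lists had narrower domains than random lists, at the percentiles 0.22, 0.35 and 0. Against random lists matched on −log10 p, the neuronal and the lung and gut lists lay within the range, at the percentiles 25.1 and 23.9.

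**Figure D3:**
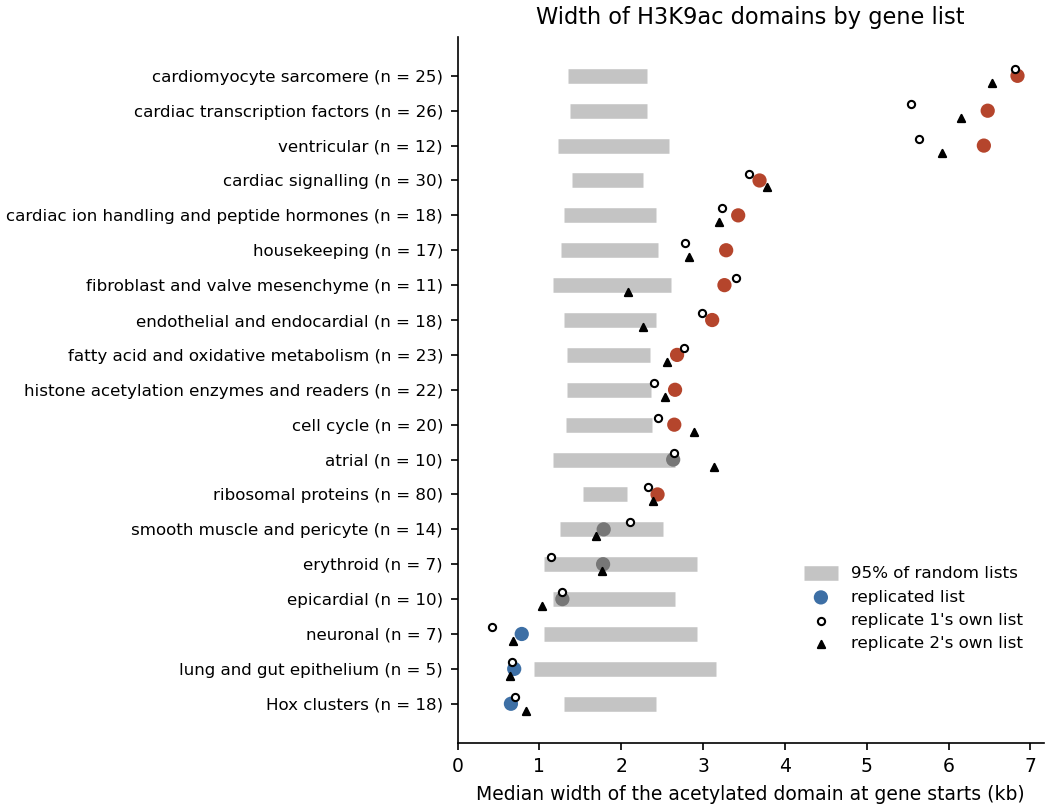
Median width of the acetylated domain at the starts of each list's marked genes (kb, large points; n is the number of marked genes). Grey bars span 95% of 10000 random lists of marked genes of the same size, and small circles and triangles give the medians in the lists of replicates 1 and 2; the sarcomere (6.84 kb), transcription factor (6.48 kb) and ventricular (6.43 kb) lists lie farthest from their bars.

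**Figure D4:**
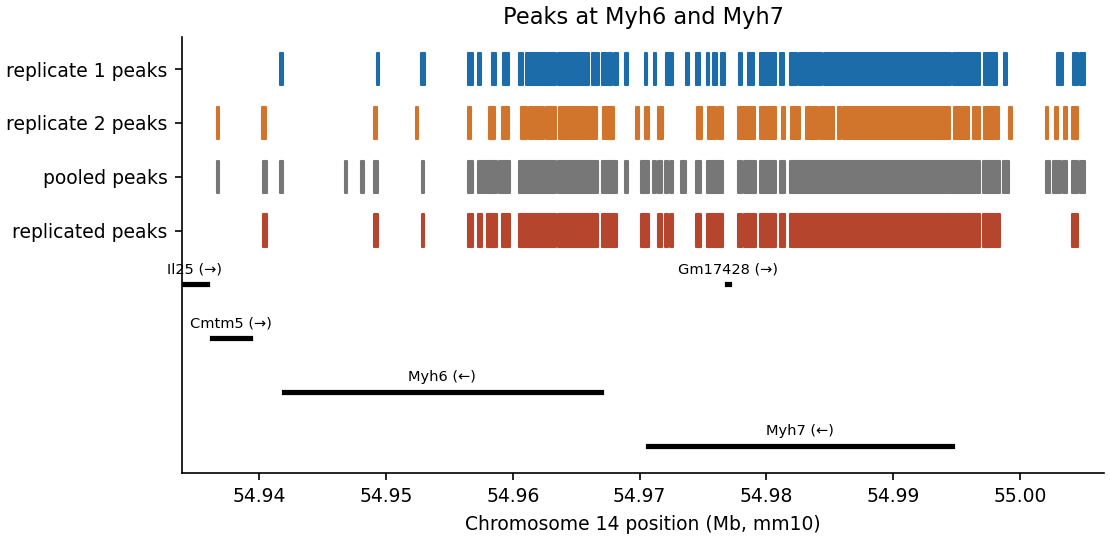
Peaks of the 4 lists over Myh6 and Myh7 on chromosome 14 (horizontal axis, Mb, mm10), with gene bodies as black lines and arrows for their strand. Blocks of peaks lie around the 5′ end of each gene, at its right end since both lie on the minus strand. The Myh6 5′ end itself falls in a gap between peaks in all 4 lists, and that of Myh7 in the lists of both replicates. The replicated peaks join into domains of 11.8 kb at Myh6 and 20.7 kb at Myh7, which span these ends.

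Peaks more than 2.5 kb from every protein-coding start, called distal here, gathered around genes of the heart muscle cell. Starts of other genes were not left out of them, nor were outer peaks of a gene's own wide domain. The random lists were not matched on domain width, so the distal counts and the domain widths are not independent results. Nor were they matched on the number or spread of a gene's starts. A gene with widely spaced starts had more sequence searched, and what this adds to the counts was not tested. Within 50 kb of a start, cardiac transcription factors had a mean of 6.08 distal peaks (1.22 in random lists with as many marked genes), sarcomere genes 5.42 (1.19), ion handling genes 3.85 (1.15) and ventricular genes 3.83 (1.22), all above the central 95% of 10000 random lists, in the replicated list and in the lists of both replicates. Those longer lists gave higher means, with 10.15 and 10.42 for transcription factors, 10.5 and 10.7 for sarcomere genes, 8.40 and 6.90 for ion handling genes and 6.58 and 8 for ventricular genes, against random means between 2.46 and 2.74. Gata4 had 17 such peaks, Nkx2-5 had 15, Jph2, which encodes junctophilin of the cardiac dyad, had 20, and Bahcc1 had 30. Genes of fatty acid metabolism (1.38), cardiac signalling (2.03), the endothelial (1.90), atrial (2.42), epicardial (0.867) and fibroblast (0.750) lists lay within the random range, although the endothelial list lay above it in each replicate's own list, at the percentiles 97.7 and 97.8, and the atrial list in that of replicate 2, at 98.01. The Hox clusters (1.59 against 0.767) and the macrophage and lymphocyte list (1.12 against 0.368) lay above it, at the percentiles 99.2 and 98.7, and olfactory receptor genes below it (0.0644 against 0.374). The Hox value was at the percentile 65.7 in the list of replicate 1, and the macrophage value at 96.6 in that of replicate 2. In the pooled list both lay within the range, at the percentiles 88.1 and 95.6.

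Of the 5 distal peaks with the highest signal values, 4 overlapped genes that do not encode proteins in the annotation used. The highest signal value, 26.4, belonged to a peak on chromosome 7 (73556344 to 73558527) over the processed transcript 1810026B05Rik, 14.5 kb from Chd2. The next lay between genes on chromosome 12 (8640762 to 8641713), 32.4 kb from Pum2, and within Lncppara on chromosome 15 (85669037 to 85673284), 61.7 kb from Ppara, a regulator of fatty acid oxidation. The other 2 lay on chromosome 2 (90916373 to 90918892), at Ptpmt1, annotated here as a processed transcript, with Kbtbd4 the nearest protein-coding gene, and on chromosome 1 (9942677 to 9944151), at the small nucleolar RNA host gene Snhg6, with Mcmdc2 the nearest protein-coding gene. All 5 overlapped a peak of each replicate. Of domains that touched no protein-coding start, the widest was 11.0 kb over the long non-coding RNA gene Gm26698, 3.03 kb from Irf2bpl (chromosome 12, 86887826 to 86898786). It was followed by 9.29 kb over Malat1 (chromosome 19, 5795308 to 5804600) and 8.43 kb over Mir1a-1, a microRNA gene of heart and skeletal muscle, and B230312C02Rik (chromosome 2, 180385530 to 180393954), 50.8 kb from Gata5. The last 2 lay in introns of Cxxc5 (8.11 kb, chromosome 18, 35834928 to 35843034) and of Myh9, a non-muscle myosin (7.99 kb, chromosome 15, 77796944 to 77804937).

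The share of marked genes rose with CpG content at the gene's 5′ end. Most genes of the heart muscle cell with few CpGs there were marked nonetheless. In the lowest tercile of observed over expected CpG, 15.3% of genes were marked (14.5 to 16.1%, Wilson), in the middle tercile 78.4% (77.5 to 79.3%) and in the highest tercile 96.6% (96.2 to 97.03%). Within the lowest tercile, 12 of 13 sarcomere genes, 6 of 8 ion handling genes, 5 of 5 ventricular genes and 4 of 5 endothelial genes were marked, with adjusted exact p = 1.04e-08, 0.000804, 0.000332 and 0.00574. Myh6, Myh7, Tnnt2 and Gata4 belong to this tercile. The tercile rests on the gene's 5′ end, whereas a gene could be marked at any of its starts. The widest domains at Myh6, Myh7 and Tnnt2 spanned the 5′ end. Those at Gata4, Notch1 and Egfl7, also of this tercile, lay at other starts, where CpG content was not measured. Of the epicardial list 2 of 6 and of the fibroblast and valve list 1 of 5 were marked there, and neither passed (adjusted exact p = 0.36 and 0.72), although 80% of the fibroblast and valve genes there were marked in replicate 2 (adjusted exact p = 0.00863) and 0% in replicate 1. Of the skeletal muscle list 1 of 8 was marked there (12.5%, adjusted exact p = 1), with 37.5% in replicate 1. None of 14 hepatocyte and none of 13 macrophage and lymphocyte genes of this tercile were marked, and at these list sizes even a count of 0 could not pass (unadjusted exact p = 0.148 and 0.24). Of 13 erythroid genes of this tercile 2 were marked (15.4%), against 15.3% of its other genes (adjusted exact p = 1), and all 11 unmarked erythroid genes lie in it. Of the 1124 olfactory receptor genes there, 1 was marked (adjusted exact p = 1.47e-85).

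The embryos were of both sexes, and genes of the X chromosome were marked less often than autosomal genes. On the X chromosome 422 of 948 genes (44.5%) were marked, against 13478 of 20780 autosomal genes (64.9%), a log2 odds ratio of -1.20 (two-sided Fisher's exact p = 1.44e-35). The value was -1.24 in the list of replicate 1 and -1.20 in that of replicate 2. The X chromosome held 4.01 replicated peaks per Mb, and the autosomes between 8.81 (chromosome 14) and 23.1 (chromosome 11). On the Y chromosome 3 of 183 genes were marked.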

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

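The tests of peak strength and of the blood cell share, and that of other copies of Nppa, were chosen only after the result was seen. Random lists matched on −log10 p were among the alternatives fixed before, but their use as a test of peak strength was not. Random lists, intervals and percentiles here describe these peak lists, and the design holds 1 group, so no explanation by a difference between groups was tested.

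A signal lay outside the list used for the main results: 1500 pooled peaks had a −log10 q of at least 5 and were missing from the replicated list. Of them 642 overlapped a peak of replicate 1 alone by at least 50%, 712 one of replicate 2 alone and 146 neither, and 28.8% lay at a protein-coding start. A further 6 replicated peaks lay on sequences outside the main chromosomes, whose genes were not analysed here.

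Sarcomere, cardiac transcription factor and ventricular genes had the widest domains. Stronger peaks did not account for this, since against random lists matched on −log10 p the lowest ratio of the 3 medians to the random median was still 3.41. Domains of neighbouring genes running together did not either, since among genes alone in their domain the lowest ratio was 3.84. With random lists matched on CpG terciles it was 3.44, and in each of these tests all 3 lists lay at the percentile 100. The sarcomere and ventricular lists share Myh7, so the 3 lists are not independent. Wide acetylation at genes of the heart muscle cell is therefore a hypothesis that these 3 technical explanations leave standing, while the share of each cell type in the tissue stays open. A gene's width was that of the widest domain at any of its starts, and no random lists were matched on the number of starts. Whether many starts widen the domains of these lists was not tested and stays open too.

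Genes of the X chromosome were marked less often than autosomal genes. Promoter CpG content was not the whole cause, since the log2 odds ratio combined over CpG terciles was -1.15 (95% interval -1.41 to -0.90). Repeated sequence alone was not either: among genes with under 10% repeated words the ratio was -0.59 (-0.88 to -0.31), with 62.7% of 612 X genes and 71.8% of 1619 of the random autosomal genes marked, although it was smaller than the -1.20 of all genes. Each was tested on its own, so how much of the difference CpG content and repeated sequence together account for was not measured. A lower X copy number in pools of both sexes may weaken peaks, since the 139 marked X genes of the highest CpG tercile had a median −log10 p at the percentile 30.6 of marked genes, against 66.5 for autosomal genes of that tercile, lower than in all random autosomal lists of that size (percentile 0). Lower activity of X genes in this tissue or on the inactive X chromosome would also give weaker peaks; it was not tested and stays open.

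Nppa and 11 of 18 erythroid genes had no replicated peak at a start, and all 11 lie in the lowest CpG tercile, where 2 of 13 erythroid genes (15.4%) and 15.3% of other genes were marked. Shared reads were argued against for Nppa, with 0% of its words repeated in the primary assembly, and for the 7 unmarked erythroid genes other than globins (median 6.35%), while for the 4 globin genes (58.9%, from 35.99 to 80.6%) they cannot be told apart from an absent peak, because the read length is not given in the sources used here. Patches and alternate loci hold 86.3% of the words at Nppa, but a loss of peaks there was argued against, since 52 of 80 random autosomal genes also held there were marked, against 1212 of 1920 others (log2 odds ratio 0.11, -0.57 to 0.78; two-sided Fisher's exact p = 0.813). A small share of blood cells in the tissue may lower the signal of the erythroid peaks that were called, since the 7 marked erythroid genes had a median signal percentile of 18.4, at the percentile 2.4 of random lists. That median is the value of Ank1, whose widest domain (chromosome 8, 23138964 to 23144113) lay far from its 5′ end at 22974844. Peaks of whole hearts cannot be assigned to blood cells, so this signal does not measure their share. Low signal was not particular to blood genes, however. The endothelial (16.0), epicardial (14.7) and smooth muscle (16.9) medians were lower still, and that of fibroblast and valve genes (22.1) was higher. Whether the 11 unmarked genes need any explanation beyond their promoter class, and what leaves Nppa without a peak, stays open.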

How the results depend on the processing

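The background without olfactory receptors and the peaks overlapping both replicates by at least 50% were chosen after the data were seen. The counts of lists called higher or lower by the gene list test, of lists with wide domains, of lists called by distal peaks and of marked genes stayed within 1.5 times under the alternatives run for them, and the X chromosome result kept its direction and its side of the threshold in all 6. For single lists under alternatives, the test of marked members lost a call in 13 cases, gained one in 6, turned direction in 6, none past the threshold, and in 190 stayed called or stayed uncalled. Domain width lost 13, gained 8 and stayed so in 129, and distal peaks lost 9, gained 5 and stayed so in 178. As log2 odds ratios, those that turned were the epicardial list with starts within 0.5 kb (-0.58), with gene 5′ ends (-0.029) and without olfactory receptors in the background (-0.083), and the fibroblast list with strict peaks (-0.027), with peaks overlapping both replicates (-0.040) and without replicate 2 (from -0.17 to 1.65 over the lists of single replicates). Strict peaks (−log10 q of at least 5) numbered 27513 pooled, 21516 in replicate 1 and 21622 in replicate 2. Replicate overlap was 43.7% and 41.4% with 50% reciprocal overlap, 86.1% and 86.4% with strict peaks, and 60.1% and 60.0% with lists of equal length. The share at starts was 68.7% with strict peaks, 38.7% in the pooled list, 44.9 to 45.9% without one replicate, 65.9% with peaks overlapping both replicates, 56.2% within 0.5 kb, 67.6% within 2.5 kb and 48.3% at gene 5′ ends. Lists with narrow domains numbered 1 with strict peaks, 5 in the pooled list, 1 with peaks overlapping both replicates and 1 with random lists matched on −log10 p. The marked share of the lowest CpG tercile was 13.97% with strict peaks, 17.0 to 17.8% without one replicate and 16.3% with CpG counted within 0.5 kb, and that of the highest tercile 96.0%, 96.97 to 97.002% and 97.3%. The cause of these changes was not tested. The depth is unknown, so what it limits was not measured.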

Other observations

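The test of microRNA genes here was chosen only after the result was seen, and other values are described without a test. Sarcomere genes had wide domains but not high signal values, which are those of whole hearts and do not give the level per cell. Among marked genes of the replicated list, their median signal percentile was 38.4, with 18 of 25 under the median, and their median width percentile 98.7. Ventricular genes were alike, at 34.4 and 98.5, and cardiac transcription factors lay at 48.8 and 98.5. Ribosomal protein genes lay at 80.1 and 72.0, and housekeeping genes at 77.7 and 86.8. Median signal percentiles were 16.0 for endothelial, 14.7 for epicardial, 16.9 for smooth muscle and 22.1 for fibroblast and valve genes. The genes with the most distal peaks within 50 kb were Casz1 and Gse1 (36 each), Tns1 (31), Bahcc1 and Mical2 (30 each), and Rbm20, a splicing factor of titin, had 27. These counts were not adjusted for the number or spread of a gene's starts.

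The replicates differed in which genes of some lists they marked. Of the fibroblast and valve list, Col3a1, Dcn, Dpt and Postn were marked in replicate 2 alone and none in replicate 1 alone. Of the Hox clusters 7 genes were marked in replicate 2 alone and 1 in replicate 1 alone, and of the neuronal list 1 and 5. These genes were named after their values were seen, and no test was made of the difference.

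Because Mir1a-1 lay in one of the widest domains at no protein-coding start, it was asked, after that result was seen, whether other heart microRNA genes carry peaks. Within 2.5 kb, 5 of 6 others did (Mir1a-2, Mir133a-1, Mir133a-2, Mir208a and Mir208b; not Mir499), against 2 of 16 microRNA genes of other tissues (Mir124a-1 and Mir124a-3; the 16 include Mir206 and Mir133b of skeletal muscle), with two-sided Fisher's exact p = 0.00432. However, Mir208a and Mir208b lie within Myh6 and Myh7, whose peaks were already known. Each Mir1a gene is a neighbour of a Mir133a gene, among them Mir133a-2 next to Mir1a-1. The genes are therefore not independent, and the exact p, which counts each as separate, is not support. Acetylation at heart microRNA genes remains a hypothesis.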
